A study of Mus musculus with 4 samples.

How the data were processed

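Chromatin immunoprecipitation followed by sequencing (ChIP-seq) for H3K27ac, the acetylation of lysine 27 on histone H3 that marks active promoters and enhancers, was carried out in MC1-ZE7 mouse embryonic stem (ES) cells. The cells were sorted by flow cytometry on the fluorescence of Emerald, a green fluorescent protein that reports Zscan4 expression in this line. There were 2 libraries from Emerald-negative (Zscan4−) cells and 2 from the bright Emerald-positive (Zscan4+) fraction, grouped by the descriptions in the labels. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be partly technical. Per the labels' protocols, the second replicate was prepared differently: its libraries were amplified before size selection and cut at 200 to 500 bp, whereas those of replicate 1 were cut at 200 to 300 bp. Neither an input nor an unspecific-antibody library was used here.

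The deposited values were RPKM (read counts scaled to the region length in kilobases and to the total reads of the library), per the file headers, rounded by the authors to 2 decimals. Reads had been handled with Bowtie and HOMER on the mouse build mm9, per the submitters' processing notes. Their versions, and how the regions were called, are not given in the sources used here. All 4 libraries were measured by the authors over one shared list of 23946 regions with identical coordinates, so values can be compared region by region. Coordinates are printed as deposited, on mm9. The files pair no region with a gene, and no mm9 annotation was used here, so regions are identified by position only and no gene, exon or promoter is assigned. The fixed design had assumed gene tables. Its 18 gene lists and the gene list tests were therefore not run, and the same limma test was applied to regions instead of genes.

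The depth behind the values was worked out from the RPKM themselves. Multiplied by region width, the values of each library fell on whole multiples of one step, taken as 1 read. Of the values below 50 reads, between 97.15% and 99.97% per library lay within 0.1 reads of a whole number. The step gave totals of 9939150 reads for Zscan4− replicate 1, 17761276 for Zscan4− replicate 2, 18284783 for Zscan4+ replicate 1 and 15920254 for Zscan4+ replicate 2. The median region held 56, 107, 79 and 102 reads in that order. A count of 0 allows up to 3 reads, which at the median width of 1111 bp is 0.272 RPKM in the shallowest library and 0.148 RPKM in the deepest. Exact 95% counting intervals and this floor cover counting error only, since reads copied by PCR are not independent molecules. Between replicates, a chi-square test of the recovered reads gave 1.91 per degree of freedom for Zscan4− and 2.93 for Zscan4+, so the replicates differed by more than sampling noise and none was counted as a repeat deposit.

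Groups were compared with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend in level, on log2(RPKM + 0.5) for regions with a mean of at least 0.5 RPKM over the 4 libraries. That minimum removed no region. P-values were two-sided and adjusted by Benjamini-Hochberg, and regions were called at an adjusted p of at most 0.05. A log2 difference is on the log2(RPKM + 0.5) scale, which understates the change of low regions. limma estimated one shared variance for regions of a given level, so standard errors hardly differ between regions. Regions named in the text are the 12 with the largest rise and the 12 with the largest fall among called regions with the same sign in both replicates. This rule, the test, its threshold and most of the alternatives were fixed before the data were examined; the parts of the rule that concern gene symbols could not be applied. Location was tested with Fisher's exact test per chromosome, and closeness of called regions with 10000 permutations of the calls within each chromosome. Both treat regions as independent, which neighbouring regions are not. Python 3.11.15 with scipy 1.17.1 was used for these.

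Alternatives were a replicate block, pseudocounts of 0.1 and 1, no minimum and a minimum of 2 RPKM, centring each library on its median, quantile normalization, a variance without trend, a threshold of 0.10, and leaving out each library in turn. The voom weights of limma on the recovered reads, and a restriction to regions wider than 228 bp, were added after the data had been seen. Replicate numbers pair the libraries, because the labels tie replicate 2 to its own preparation. Across regions, the differences between replicates 1 and 2 correlated at 0.35 between the groups.

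The fit was tested on simulated data: reads for the 23946 regions were drawn at the libraries' own depths and shares of reads in regions, with 200 regions changed. At 4-fold, 50 of 50 raised and 38 of 50 lowered regions were called. At 2-fold, 0 of 50 raised and 4 of 50 lowered regions were called, and 2 of 23746 unchanged regions were called. With the replicate block, 50 of 50 regions raised and 49 of 50 lowered 4-fold were called, 0 of 50 raised and 11 of 50 lowered 2-fold, and 7 unchanged ones. With quantile normalization, 39 of 50 regions raised 2-fold and 27 of 50 lowered 2-fold were called, with 36 unchanged ones. Simulated reads had a single dispersion of 0.011 and no effect of replicate preparation. In the real libraries the replicate differences correlated at 0.35 between the groups. The counts of unchanged regions called may therefore not carry over to the real libraries. Each simulated region started from its share of the reads pooled over all 4 libraries. The lowest mean over the 4 libraries was 1.19 RPKM, so rises that start near the floor were not simulated.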

Results

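H3K27ac was profiled in sorted mouse ES cells to compare Zscan4+ with Zscan4− cells of one culture line. Zscan4 is a family of zinc-finger genes switched on for a short time in a small part of an ES culture and in the 2-cell embryo. Each group had 2 libraries, with 9939150 and 17761276 reads for Zscan4− replicates 1 and 2, and 18284783 and 15920254 for Zscan4+ replicates 1 and 2. The 23946 listed regions lay on 21 chromosomes, with a median width of 1111 bp and a range of 214 to 7077 bp. They held 16.74% and 17.88% of the reads of the Zscan4− libraries, a mean of 17.31% ± 0.81 (SD, n = 2). In the Zscan4+ libraries they held 12.97% and 19.14%, a mean of 16.06% ± 4.36 (SD, n = 2). The difference between the groups was smaller than the spread between the Zscan4+ replicates, and with 2 libraries against 2 an exact two-sided permutation test cannot go below p = 0.333.

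Over the listed regions, H3K27ac levels correlated less between the 2 cell states than between replicates. Across regions, the log2 levels of the Zscan4− replicates correlated at Pearson r = 0.957 (Spearman rho 0.903), and those of the Zscan4+ replicates at r = 0.94 (rho 0.896). Between a Zscan4− and a Zscan4+ library, r lay between 0.696 and 0.737. These are correlations across regions, which are not independent replicates. How the regions were called is not stated, and a list picked in each group would lower the correlation between groups. Replicate 2 lay above replicate 1 by a median of 0.3 on the log2 scale in the blocked limma fit, in which 2 regions were higher and 0 lower in replicate 2, with 2491 at an unadjusted p under 0.05.

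Of the 23946 regions, 1917 (8.0%) were higher and 1632 (6.8%) were lower in Zscan4+ cells by limma at an adjusted p of at most 0.05. In this fit the rises were larger than the falls. Higher regions had a median log2 difference of 1.96, and 925 of them rose at least 4-fold on the log2(RPKM + 0.5) scale, a limit chosen after the data had been seen. Lower regions had a median of -1.15, and 16 of them fell at least 4-fold. The count past 4-fold lower was 114 with quantile normalization, against 504 higher, 56 with a pseudocount of 0.1, 67 with voom on the recovered reads, an alternative added after the data had been seen, and 89 without Zscan4+ replicate 2. The median difference of the higher regions was 1.75 in replicate 1 and 2.12 in replicate 2, and that of the lower regions was -1.41 and -0.94. Both replicates showed the same direction in 1916 of the higher and 1630 of the lower regions, which the selection of called regions favours, and in 16930 of all 23946 regions. With the replicate block, limma called 2238 regions higher and 2603 lower, and the counts past 4-fold stayed at 925 and 16. Over all regions the median difference was -0.17, and it was -0.37 in replicate 1 and 0.05 in replicate 2. The counts in both directions depend on the scaling of the libraries: after centring each library on its median, 3375 regions were called higher and 3622 lower, and the median standard error was 0.21 in place of 0.36.

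**Figure D1:**
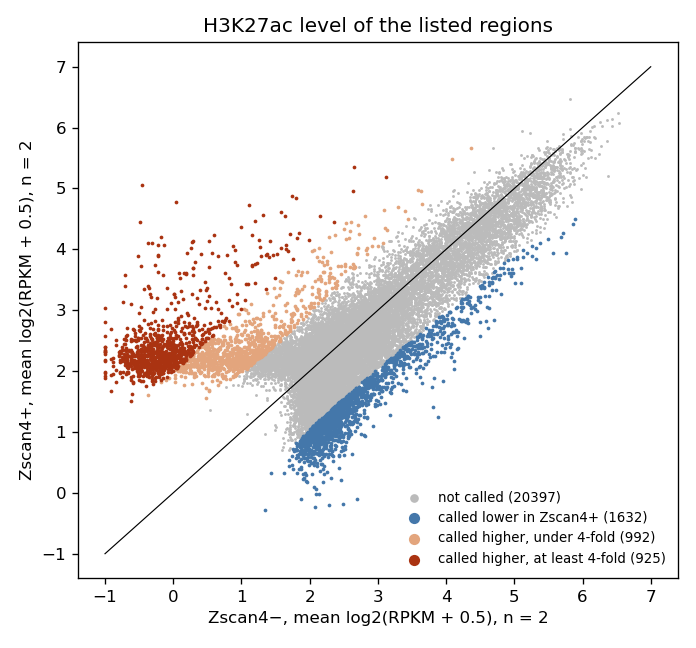
H3K27ac level of each of the 23946 regions, as the mean log2(RPKM + 0.5) of the 2 Zscan4− libraries (x axis) against that of the 2 Zscan4+ libraries (y axis), with the line of equal level and the number of regions in each class. The 925 regions called at least 4-fold higher lie above the line at the left, and the 1632 lower regions lie below it.

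The 925 regions that rose at least 4-fold went from a level near the floor to that of an ordinary region of the list. Their median was 0.38 and 0.39 RPKM in Zscan4− replicates 1 and 2, which is 3 and 7 reads, and 3.86 and 5.27 RPKM in Zscan4+ replicates 1 and 2, which is 68 and 82 reads. The median over all regions was 4.77 and 5.08 RPKM in the Zscan4− libraries, and 3.8 and 5.48 RPKM in the Zscan4+ libraries. Using limits chosen after the data had been seen, 777 regions were below 1 RPKM in both Zscan4− libraries and above 3 RPKM in both Zscan4+ libraries. The reverse, below 1 RPKM in both Zscan4+ and above 3 RPKM in both Zscan4− libraries, held for 18 regions. In all, 917 regions were below 1 RPKM in both Zscan4− libraries and 25 in both Zscan4+ libraries. In every listed region the higher group mean was at least 1.95 RPKM, so a region low in either group was higher in the other. The 777 and 18 therefore depend on which sites the list holds. Without Zscan4− replicate 1, 890 regions were called at least 4-fold higher, and without Zscan4+ replicate 2 there were 750. With a pseudocount of 1 in place of 0.5, 449 regions were called at least 4-fold higher, all among the 925, and with quantile normalization 504, of which 498 were among the 925. Of the 925, 925 and 924 were still called higher.

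**Figure D2:**
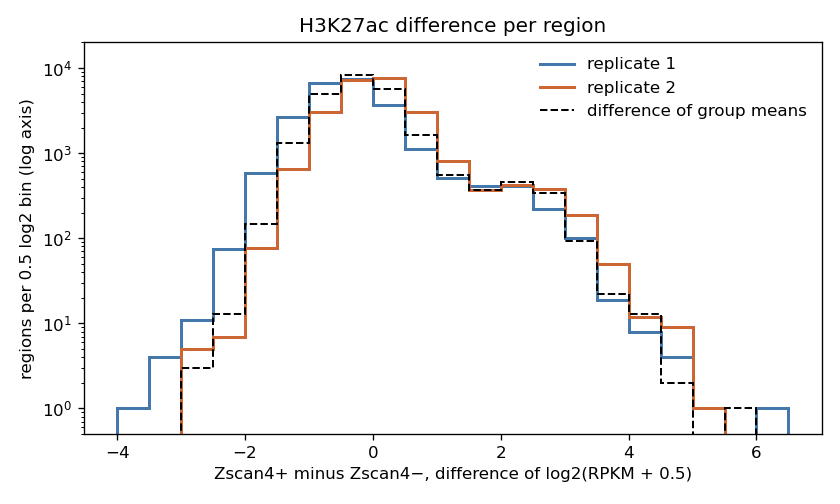
Number of regions (log axis) per 0.5-wide bin of the difference between Zscan4+ and Zscan4− cells in log2(RPKM + 0.5), for replicate 1, replicate 2 and the difference of the group means. The difference of the means has 367 regions from 1.5 to 2.0 and 453 from 2.0 to 2.5, and the lower side has no such shoulder.

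The region with the largest rise, R20020, lies on chromosome 7 from 111919938 to 111920243. It had 0.28 ± 0.39 RPKM in Zscan4− and 32.75 ± 0.59 RPKM in Zscan4+ cells (SD, n = 2), a log2 difference of 5.52 with a standard error of 0.35 (limma adjusted p = 2.3e-50). That p rests on the variance shared between regions. The limma adjusted p of R20020 was 5.9e-06 with median centring and 0.00012 with quantile normalization, so its size depends on the scaling. The pooled counts were 3 reads in Zscan4− and 342 in Zscan4+ libraries, a ratio of 92.3 relative to library totals with an exact 95% counting interval of 31.3 to 449.9. R14148, on chromosome 3 from 93623645 to 93623860, rose from 0.26 ± 0.37 to 21.32 ± 2.09 RPKM, a log2 difference of 4.93. R22519, on chromosome 9 from 46254705 to 46255004, rose from 0.55 ± 0.29 to 29.5 ± 17.41 RPKM, a log2 difference of 4.74, and its level in Zscan4+ cells differed between replicates, at 17.19 and 41.81 RPKM. R01921, on chromosome 10 from 61958214 to 61958456, rose from 0.35 ± 0.49 to 17.06 ± 5.59 RPKM. Chromosome 9 held 2 more, R22454 from 42792673 to 42792887 with a log2 difference of 4.42 and R22876 from 75302782 to 75302996 with 4.39. The other 6 were R20684 (chromosome 8, 19160690 to 19160904), R06836 (chromosome 14, 51615451 to 51615665), R13343 (chromosome 2, 168922967 to 168923196), R11703 (chromosome 19, 61208240 to 61208500), R19681 (chromosome 7, 68832057 to 68832271) and R12786 (chromosome 2, 126445672 to 126445892). These 12 regions were between 214 and 305 bp wide. They had mean levels of 0.12 to 0.55 RPKM in Zscan4− and 12.78 to 32.75 RPKM in Zscan4+ cells, with log2 differences of 4.14 to 5.52, standard errors of 0.35 to 0.36 and adjusted p of at most 1.9e-28. Each had 1 to 5 pooled reads in the Zscan4− libraries, so the size of its rise depends on the pseudocount.

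Taken by their medians, the 1632 regions that fell in Zscan4+ cells went from about the typical level of the list to an intermediate level, not to the floor. Their median was 4.98 and 5.04 RPKM in Zscan4− replicates 1 and 2, against 1.6 and 2.5 RPKM in Zscan4+ replicates 1 and 2. The 16 that fell at least 4-fold went lower, to medians of 0.67 and 0.83 RPKM in Zscan4+ replicates 1 and 2, which is 3.5 reads in each. The lowest values differed between the groups. In Zscan4− replicates 1 and 2, 110 and 41 listed regions were at 0 RPKM. The minimum was 0.17 and 0.25 RPKM in Zscan4+ replicates 1 and 2. No input library was used, so how far this limited the size of the falls was not tested. The largest fall was at R18727 on chromosome 6, from 125826799 to 125827327, with 5.97 ± 0.45 RPKM in Zscan4− and 0.44 ± 0.11 RPKM in Zscan4+ cells (SD, n = 2), a log2 difference of -2.79 with a standard error of 0.37 (limma adjusted p = 3.3e-12). Its pooled counts were 86 reads in Zscan4− and 8 in Zscan4+ libraries, 13.27 times more in Zscan4− cells relative to library totals, with an exact 95% counting interval of 6.44 to 31.73. R07813, on chromosome 15 from 74350472 to 74350700, had 5.28 ± 1.89 and 0.4 ± 0.22 RPKM, a log2 difference of -2.67. R09127, on chromosome 17 from 4626258 to 4626811, had 13.58 ± 2.65 and 2.34 ± 1.35 RPKM, a log2 difference of -2.39. R13138, on chromosome 2 from 156516336 to 156516564, had 16.78 ± 0.01 and 3.59 ± 0.01 RPKM, a log2 difference of -2.08. The other 8 were R13442 (chromosome 2, 180012308 to 180012536), R20317 (chromosome 7, 137506289 to 137506517), R10643 (chromosome 18, 42528337 to 42528837), R01880 (chromosome 10, 59331352 to 59331580), R16863 (chromosome 5, 89965130 to 89965358), R09046 (chromosome 16, 91727454 to 91727689), R16410 (chromosome 5, 22292157 to 22292385) and R00641 (chromosome 1, 90480670 to 90480898). All 12 had log2 differences between -2.79 and -2.08 and adjusted p of at most 5.9e-07. Their pooled reads in the Zscan4+ libraries ran from 3, at R07813 and R20317, to 43 at R09127. Where reads were few, the size of the fall depends on the pseudocount. The counts of lower and higher regions depended on single libraries, and so did the precision. The median standard error was 0.36 in the main fit, 0.65 without Zscan4− replicate 1 and 0.64 without Zscan4− replicate 2. It was 0.26 without Zscan4+ replicate 1 and 0.27 without Zscan4+ replicate 2. The median log2 difference of all regions was -0.17, -0.21, -0.12, 0.09 and -0.42 in the same order. The drop in lower calls without a Zscan4− library thus came with a larger standard error.

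**Figure D3:**
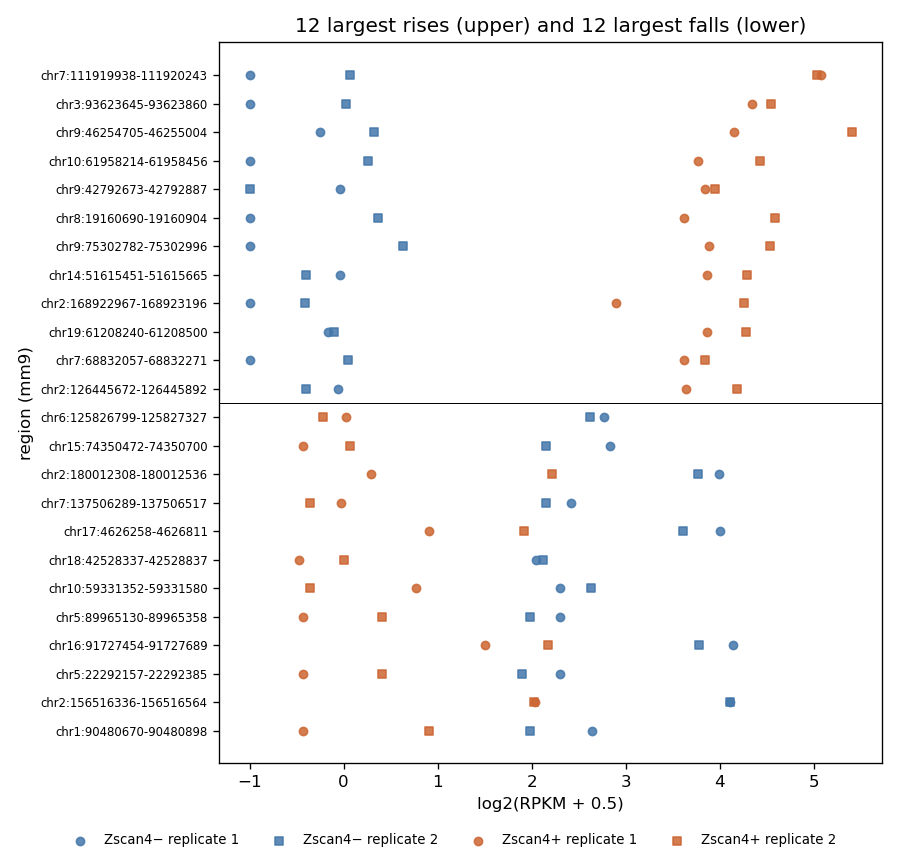
Level of the 12 regions with the largest rise (above the line) and the 12 with the largest fall (below it) in each of the 4 libraries, in log2(RPKM + 0.5), with mm9 positions on the y axis. In each region above the line both Zscan4+ libraries lie above both Zscan4− libraries, and in each region below it both lie below.

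Rises of at least 4-fold were found on all 19 autosomes and on the X chromosome, and no chromosome differed from the rest after adjustment. Their share ran from 2.38% of regions on chromosome 17 (odds ratio 0.59, 95% interval 0.39 to 0.88, Fisher's exact p = 0.0057, adjusted p = 0.073 over 40 tests) to 5.07% on chromosome 12 (odds ratio 1.35, 0.97 to 1.83, exact p = 0.062, adjusted p = 0.35). Falls were less frequent on the X chromosome, at 19 of 603 regions or 3.15% against 6.91% elsewhere (odds ratio 0.44, 0.26 to 0.69, Fisher's exact p = 0.00011, adjusted p = 0.0043). They were more frequent on chromosome 15, at 91 of 958 regions or 9.5% against 6.7% elsewhere (odds ratio 1.46, 1.16 to 1.83, Fisher's exact p = 0.0013, adjusted p = 0.026). For higher calls the odds ratio was 0.75 (0.52 to 1.05) on the X chromosome and 0.73 (0.55 to 0.96) on chromosome 15. Without Zscan4− replicate 1 or replicate 2 the odds ratio of a lower call on the X chromosome was 0, with upper limits of 1.15 and 2.5. On chromosome 15 it was 1.41 (0.56 to 3.02) and 0.84 (0.1 to 3.19). These intervals hold both 1 and the values of the main fit, so they do not tell whether the differences depend on those libraries.

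Regions that changed in the same direction lay near each other more often than calls permuted within each chromosome. Of the 925 regions that rose at least 4-fold, 146 (15.8%) had another within 50 kb, against 96.5 in permutations of the calls within chromosomes (1.51 times, one-sided permutation p = 0.0002). Of the 1917 higher regions 489 had such a neighbour, against 381.3 in permutations (1.28 times), and of the 1632 lower regions 483 against 291.6 (1.66 times). Both of these reached p = 0.0001, the smallest that 10000 permutations can give. The permutations treat neighbouring regions as independent and did not keep their level. Of the 925 regions, 763 were among the 5993 regions of lowest mean RPKM (1.18 to 3.47). The excess therefore does not show by itself that neighbouring sites change together. Chained at gaps of at most 50 kb, 4 runs held at least 5 called regions; this number and the 50 kb distance were chosen after the data had been seen. Chromosome 1 from 90480670 to 90602912 held 6 listed regions, all 6 lower, with a mean of 7.3 and 7.34 RPKM in Zscan4− replicates 1 and 2 and of 1.91 and 3.61 RPKM in Zscan4+ replicates 1 and 2. On chromosome 15, 5 of the 7 listed regions from 75913095 to 76039393 were lower, at log2 differences of -1.5 to -0.96. On chromosome 13, 5 of the 6 listed regions from 107567980 to 107704072 were higher, with a mean of 2.0 and 1.95 RPKM in the Zscan4− libraries and of 6.74 and 9.28 RPKM in the Zscan4+ libraries. On chromosome 17, all 5 listed regions from 17627784 to 17646700, a span of 18.9 kb, were higher at log2 differences of 0.95 to 1.51, with adjusted p of at most 0.048.

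**Figure D4:**
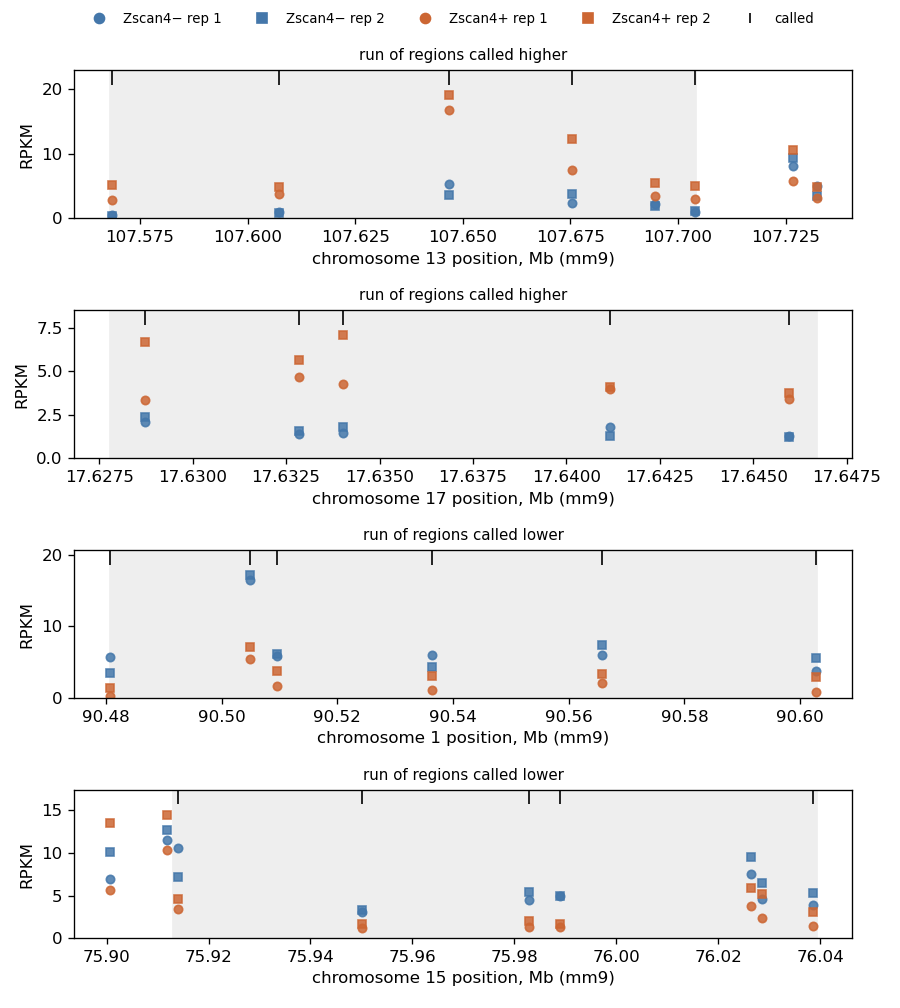
RPKM of each listed region (y axis) against its mm9 position in Mb (x axis) in the 4 runs of at least 5 called regions, shaded, with 30 kb on each side where regions are listed; points are single libraries and black ticks mark called regions. In the runs on chromosomes 13 and 17 the Zscan4+ points lie above the Zscan4− points at called regions, and in those on chromosomes 1 and 15 they lie below.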

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

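Of 417 values of the 24 named regions under the 18 other settings, 0 reversed and 414 stayed past the threshold. Their selection as the largest called changes of the same libraries favours this. Named regions of 228 bp or narrower have no value under the restriction to wider regions. The other 3 values, all in leave-one-out fits, were of R13138 and R09046, both lower. The log2 difference of R13138 was -2.08 without Zscan4− replicate 1 and without Zscan4− replicate 2, as in the main fit. That of R09046 was -1.94 without Zscan4− replicate 1, against -2.12. Higher calls (1917) numbered 3307 with quantile normalization, 5168 with the replicate block and quantile normalization together, 3375 with median centring and 3785 with voom scaled to the reads in regions, and 1101 to 3119 when one library was left out. Lower calls (1632) numbered 2603 with the replicate block, with or without the minimum, 3278 with quantile normalization, 5529 with the block and quantile normalization, 3622 with median centring, 3791 with voom scaled to reads in regions, 3676 with the block and voom, 2502 at a threshold of 0.10, and 59 to 7547 when one library was left out. Calls at least 4-fold higher (925) numbered 504 with quantile normalization, with or without the block, and 449 with a pseudocount of 1, and 750 to 1082 when one library was left out. Calls at least 4-fold lower (16) numbered 114 with quantile normalization, with or without the block, 56 and 4 with pseudocounts of 0.1 and 1, 10 with median centring, 67 and 35 with voom on recovered totals and on reads in regions, 53 with the block and voom, 7 among regions wider than 228 bp, and 12 to 89 when one library was left out. Quantile normalization gives all libraries one distribution, and so raises the lowest Zscan4− values; for the other settings the cause was not tested. With one library of a group left out, the lone library is assumed to vary like the other group. Under the replicate block all 1917 higher and 1632 lower calls were kept. The voom settings and the width restriction were chosen after seeing the data. No minimum on RPKM changed nothing, since the minimum of 0.5 removed no region. The gene list alternatives and one row per gene symbol were not run, since regions carry no gene names. Depth limits the falls and rises near the floor, where the median region of the 925 had 3 and 7 reads in the Zscan4− libraries.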

Other observations

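The tests of region width, of the large rises and of lower calls near chromosome ends were chosen after the result was seen; those of higher calls near chromosome ends and of paired gaps were written before. Within 5 Mb of the last listed region of a chromosome, 128 of 1119 regions (11.44%) fell in Zscan4+ cells, against 6.59% elsewhere (odds ratio 1.83, 95% interval 1.5 to 2.22, Fisher's exact p = 6e-09). Fisher's test treats regions as independent. Of the 1632 lower regions, 483 had another within 50 kb, against 291.6 in permutations, so the interval and p understate the uncertainty. The size of the excess near the ends varied when single libraries were left out. The odds ratio was 1.13 (0.86 to 1.47) without Zscan4+ replicate 1 and 1.52 (1.34 to 1.72) without Zscan4+ replicate 2. It was 1.77 (0.82 to 3.38) without Zscan4− replicate 1 and 1.09 (0.22 to 3.37) without Zscan4− replicate 2. These last intervals hold both 1 and 1.83, so they do not tell whether the excess depends on those libraries. On the Y chromosome 4 regions were listed, of which 1 was called higher.

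For the 925 regions that rose at least 4-fold, 3 technical explanations were weighed. The 4-fold limit cuts a continuous range of differences, with 367 regions from 1.5 to 2.0 and 453 from 2.0 to 2.5. Noise between libraries would not be expected to repeat in a replicate with no library in common, but both replicates share the region list. In every listed region the higher group mean was at least 1.95 RPKM, so a repeat does not test how the list was chosen. Of the 763 regions at least 4-fold higher in replicate 1, 685 (89.8%) were at least 4-fold higher in replicate 2, where 4.4% of all regions were, and with the replicates exchanged the share was 64.7%. Of the 90 regions at least 4-fold lower in replicate 1, 5 (5.6%) were so in replicate 2, where 0.1% of all regions were, and with the replicates exchanged it was 5 of 14 (35.7%). The low depth of Zscan4− replicate 1 does not account for most of it, since 89.1% of the 925 stayed called and at least 4-fold higher without that library. One scaling factor per library would move all regions alike, but the median log2 difference of all 23946 regions was -0.17 (quartiles -0.53 and 0.22). With only 925 regions past 4-fold, the upper quartile could not have reached 4-fold, so these values are not a separate test. Centring each library on its median removes such a factor. It left 1001 regions called at least 4-fold higher, among them all 925. An earlier test on scaling, by quantile normalization, was replaced after its result was seen: 498 of the 925 stayed at least 4-fold higher, which decided nothing, and 924 stayed called higher. A list that held more sites from Zscan4+ than from Zscan4− cells could still make rises more numerous than falls, because how the regions were called is not stated, and a real difference between the sorted states remains a hypothesis.

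Narrow regions split by their exact width. The 422 regions of exactly 214 bp had a median log2 difference of 0.42, with 119 called higher and 0 lower. The 721 regions of exactly 228 bp had a median of -0.42, with 4 called higher and 131 lower. The medians lay 0.84 apart. A candidate explanation is that peaks were called separately in each group with a different smallest width, so that the width tells the group in which a narrow region was found, and its difference is then partly a result of how it was selected. Among the 12 regions with the largest rise 5 were 214 bp wide, and among the 12 with the largest fall 8 were 228 bp wide. The 22698 regions wider than 228 bp gave 1781 higher and 1531 lower calls, with 854 at least 4-fold higher and 7 at least 4-fold lower. Most large rises were thus not in narrow regions. Separate calling in each group could also have selected wider regions, which this restriction cannot test.

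The excess of lower calls near distal chromosome ends does not come only from a uniform offset of Zscan4+ replicate 1, the library with the smallest share of reads in regions. Settings that remove such an offset kept the excess, with an odds ratio of 1.43 (1.22 to 1.67) after median centring, 1.48 (1.26 to 1.73) after quantile normalization and 1.44 (1.24 to 1.67) with voom scaled to reads in regions. The interval lay above 1 in 16 of 19 settings, but most of these refit the same libraries, so they are not separate tests. Whether the excess rests on other properties of Zscan4+ replicate 1 stays open. Without it the interval of the odds ratio of 1.13 reached 1, but so did those without Zscan4− replicate 1 (1.77, 0.82 to 3.38) and replicate 2, which rest on 10 and 3 lower calls near the ends. Without Zscan4+ replicate 2 it was 1.52 (1.34 to 1.72). The median log2 difference near the ends was -0.5 against -0.37 elsewhere in replicate 1, and 0.01 against 0.05 in replicate 2. Gene density and base composition near the ends were not tested.

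Because Zscan4 has been linked to telomeres, it was asked whether distal chromosome ends gain the mark. They did not show a gain: the odds ratio of a higher call within 5 Mb of the last listed region was 0.81 (0.63 to 1.03), and it ranged from 0.74 to 1.0 over the 19 settings. No setting had an interval above 1. The interval lay below 1 in 6 of the 19, among them the replicate block (0.78, 0.61 to 0.98), median centring (0.75, 0.62 to 0.91) and quantile normalization (0.78, 0.64 to 0.95). The tables thus argue against a gain, while a depletion depends on the setting, and the intervals treat neighbouring regions as independent. The limit written before the result was an odds ratio of at most 1; that an interval should also lie below 1, in the main or the blocked fit, was added after it was seen.

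A further hypothesis was that large rises mark both ends of a repeated element several kilobases long, such as the MERVL endogenous retrovirus known to be active in 2-cell-like ES cells. Neighbouring regions that rose at least 4-fold would then lie 5 to 8 kb apart. There were 8 such pairs, against 5 at 2 to 5 kb and 0 at 8 to 11 kb, and the mean in 10000 random draws of as many regions per chromosome was 3.89, with an upper limit of 8 on their central 95% range. The count did not exceed that limit, so the test leaves the hypothesis open. No sequence or repeat annotation was used here.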
